A study of Arabidopsis thaliana with 16 samples.

How the data were processed

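The RNA samples came from Arabidopsis thaliana of ecotype Columbia 0, either wild type (WT) or the psag mutant, which lacks the photosystem I protein PSI-G. Total RNA was measured on arrays of 3439 probes. Of the 16 arrays, 8 were labelled WT and 8 psag, each with a replicate number from 1 to 8. The labels name no tissue, age, light condition, dye or membrane, and they do not say whether replicates came from separate plants.

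The deposited values are probe intensities on a linear scale from 0 to 100, a unit inferred from the values. The brightest probe was at 100 on 15 of the 16 arrays, within a tolerance of 0.001, and 2 probes shared that value on 6 arrays, so 100 can be a ceiling. Sums per array ranged from 2314 to 3460, so the listed values do not share a common total. Exact zeros made up 13.0% to 16.5% of the probes of an array, and 130 probes were listed at 0 on all 16 arrays. How the authors scanned, background-corrected and scaled the intensities is not given in the sources used here. Medians of the deposited intensities lay between 0.172 and 0.347 per array. Because no background or detection measure was analysed here, a value of 0 is described only as listed at 0. The number of arrays limits the precision.

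Probes were named through GEO's platform annotation, and symbols were updated through gene identifiers in a RefSeq gene table of assembly TAIR10.1. A single gene was listed for 692 probes, several genes for 870 and none for 1877. Of the 692, 690 matched the gene table. No gene is named from a probe with several genes. The genome build behind the probes is not given in the sources used here, so no positions are printed. No probe was named as PSAG, the gene mutated here, so the check of the labels by the targeted transcript was not possible.

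Intensities were taken as log2(intensity + pseudocount), with the 5th percentile of the positive intensities, 0.0407, as the pseudocount. A fold change is therefore on that scale and understates the change of dim probes. Array medians spanned 0.87 on this scale, above the limit of 0.5 fixed for it, and the arrays were quantile normalized. The median change of all probes under quantile normalization, median centring and no normalization stayed within 0.02 of 0 on the log2 scale. For a locus with several probes, which concerned 1 locus, the probe with the highest mean was kept, and 3438 probes were tested.

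Neighbouring replicates (1 and 2, 3 and 4, 5 and 6, 7 and 8) deviated together from their group mean. For 14 of the 16 arrays the closest array of the group was this neighbour, and the exceptions were WT replicates 3 and 4. Correlations of the deviations ran from 0.45 to 0.73 in the 4 psag pairs. In WT they were 0.32, -0.12, 0.09 and 0.54, where unrelated arrays would give about -0.14. That value does not hold for psag, because the psag mean includes replicates 7 and 8, which stood apart from all other arrays. This raises the correlations among the other psag arrays, so the psag values overstate how far neighbours agree. The labels do not mention such pairs. Each pair was averaged as 1 measurement, which left 4 measurements per genotype. The averaging was chosen after these correlations were seen, and it is weakly founded for WT replicates 3 and 4. If neighbours are in fact separate samples, n = 4 understates the replication. In either case the p-values measure the spread between these measurements, which may be technical.

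Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment, an adjusted p threshold of 0.05 and no fold minimum. Gene lists with at least 3 measured members were tested among single-gene probes with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Differences between complexes were tested with exact two-sided permutation tests of the genotype labels. On simulated data with 4 against 4 measurements, 3438 probes and 200 changed ones, the procedure recovered 41% of probes changed by 1 on the log2 scale and 77% of those changed by 2, with 6 false calls. With 3 against 4 measurements it recovered 52% and 82%, with 9 false calls. The simulated noise was independent between probes and measurements and had the same SD in both genotypes. These figures therefore do not cover a measurement that stands apart, or conditions shared between arrays.

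Before the data were examined, 20 gene lists holding 326 loci were fixed, and 19 of those loci had a probe of their own. Only 1 of these lists, plastid ribosomal proteins, reached 3 measured members, and 11 had none. Another 9 lists were written after the gene names on the array were known and before any test. Genes were named by a rule fixed in advance: every measured subunit of photosystem I or its antenna, up to 12 loci per direction past the threshold with a level above the median of all probes, up to 4 passing members per list, and the 5 loci with the smallest p where fewer than 5 passed. The same rule was applied to a fit without psag replicates 7 and 8, which was added after these arrays were seen to stand apart. Alternatives covered the pseudocount (1st and 20th percentile), the normalization, dim probes, limma-trend, array weights, a fold minimum of 1.5, and single arrays left out. They also covered the handling of pairs with a random block (statmod 1.5.0), and a block joining the averaged WT and psag pairs of the same numbers. Alternatives added after seeing the data left out each pair, took all 16 arrays as separate replicates, or left out probes listed at 0 throughout.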

Results

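The data set compared transcript levels between WT Arabidopsis and the psag mutant, which lacks PSI-G, a small membrane subunit of photosystem I. The 16 arrays gave 4 measurements per genotype after neighbouring replicates were averaged. The intensities of an array summed to between 2314 and 3460. The median SD of a probe across measurements was 0.29 in WT and 0.37 in psag on the log2 scale. Correlations between the 8 measurements were 0.934 to 0.980, except for those of psag replicates 7 and 8, which were 0.819 to 0.852. Without that pair, the median SD in psag was 0.18.

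**Figure D1:**
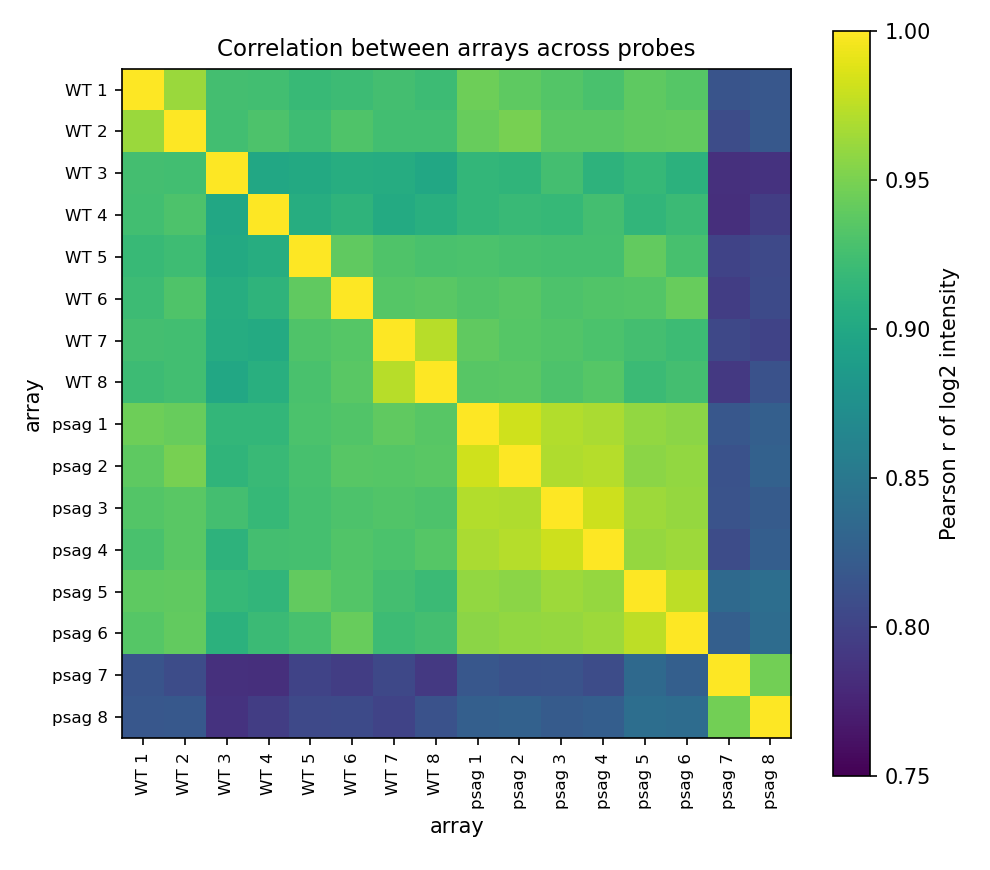
Pearson correlations across probes of quantile normalized log2 intensities between the 16 arrays, with arrays on both axes and the colour scale from 0.75 to 1. The arrays of psag replicates 7 and 8 correlated with each other at 0.947 and with the other 14 arrays at 0.783 to 0.840.

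The first question was which transcripts differed between psag and WT. AT5G52810, the locus of the reductase SARD4 in pipecolic acid synthesis, rose most among the named genes. Its log2 intensity was 0.86 ± 0.06 in WT and 2.60 ± 0.32 in psag (SD, n = 4 each), a 3.34-fold difference (limma, adjusted p = 0.0175). SIS, named for a salt-induced serine-rich protein, rose 1.70-fold, from -1.75 ± 0.09 to -0.98 ± 0.11 (SD, n = 4 each; limma, adjusted p = 0.0175). AT1G06730 fell from 1.27 ± 0.06 to 0.58 ± 0.15 (limma, adjusted p = 0.0408, SD, n = 4 each), and its level was 1.62-fold higher in WT. AT4G23080 fell from -0.01 ± 0.12 to -0.77 ± 0.15 (limma, adjusted p = 0.0421, SD, n = 4 each) and was 1.69-fold higher in WT. AT1G28150, with the next smallest p among single-gene probes, was 1.03 ± 0.18 (SE) higher in psag on the log2 scale and did not pass (limma, adjusted p = 0.0855). For all 5 of these loci, the 4 psag measurements lay on one side of the 4 WT measurements.

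**Figure D2:**
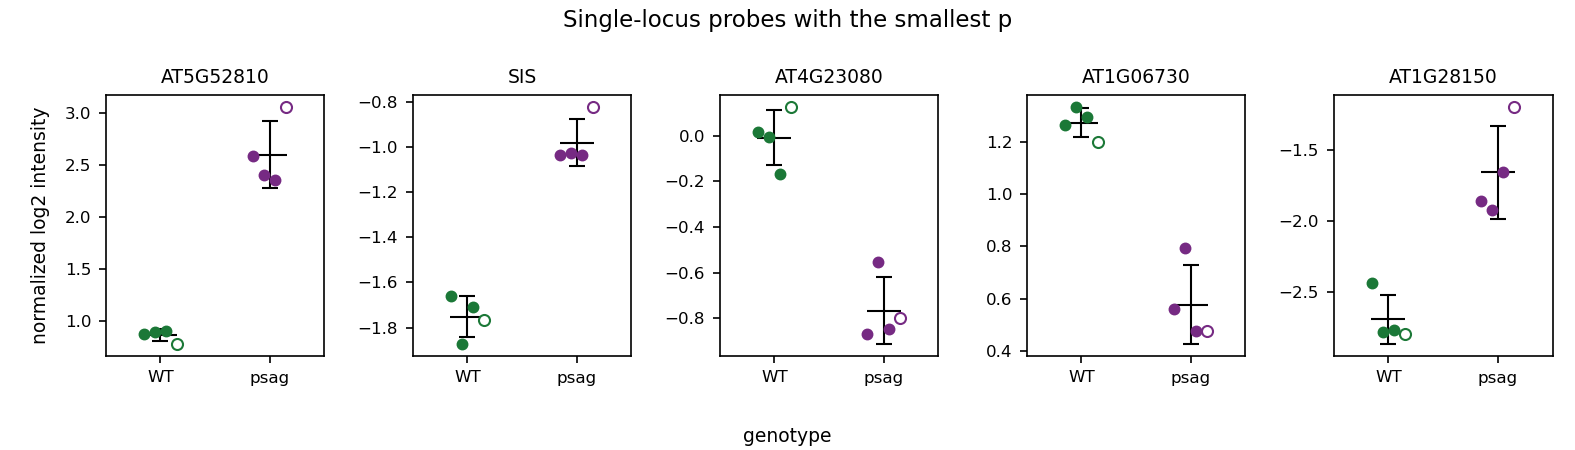
Normalized log2 intensity (vertical axis) of the 5 single-gene probes with the smallest p, by genotype, with each point a measurement averaged from 2 arrays. Open symbols mark replicates 7 and 8, and bars give the mean and SD of 4 measurements; for AT5G52810 the means were 0.86 in WT and 2.60 in psag.

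In all, 11 of 3438 probes passed the threshold, 9 higher and 2 lower in psag, with differences of 1.62-fold to 3.34-fold. Of the 11, 4 had a single named gene, 1 had several and 6 had none listed. At an unadjusted p under 0.05 there were 437 probes, or 12.7%. The groups did not overlap for 345 probes, or 10.0%, where chance gives 2.86%. The count of 11 was not stable: it was 0 after median centring in place of quantile normalization and 2 when the 130 probes listed at 0 throughout were left out. It was 113 with pairs as a random block and 330, of which 195 were higher, with all 16 arrays as separate replicates. With averaged pairs of the same numbers as a block, 1 probe passed and 0 of the 11 did. The 4 named genes then had limma adjusted p = 0.262. Arrays of one number resembled each other across genotypes: 6 of 8 in each group correlated best with their own number. For the averaged pairs that the block joins, deviations correlated across genotypes at 0.051, 0.108, 0.166 and 8.8e-04.

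Without psag replicates 7 and 8, a setting chosen after seeing the data, 82 probes passed, 55 higher and 27 lower, and these included all 11. Single genes were named for 16 of the 82. Among those that rose, AT5G11650 differed most after AT5G52810, with log2 intensities of -0.31 ± 0.22 in WT (n = 4) and 1.14 ± 0.17 in psag (SD, n = 3; limma, adjusted p = 0.0152). AT4G27250 rose 1.99-fold (limma, adjusted p = 0.00227). OTP70, a pentatricopeptide repeat protein of organelle transcript processing, rose 1.78-fold (limma, adjusted p = 0.0360). RAP74, a subunit of the general transcription factor TFIIF, rose 1.53-fold (limma, adjusted p = 0.0295). AT2G35390, AT3G07790 and AT4G16410 rose 1.61-fold, 1.45-fold and 1.42-fold. AT3G09080 fell by 1.02 on the log2 scale (limma, adjusted p = 0.00879), AT3G20150 fell by 0.52 and AT5G62840 fell by 0.37. With all measurements AT3G20150 was at -0.94, AT2G35390 at 0.11 and AT4G16410 at 0.28 on the log2 scale. None of the 10 genes named only without psag replicates 7 and 8 passed with all measurements. Replicates 7 and 8 themselves lay on the same side of WT for 11 of the 14 passing genes that the naming rule took. The exceptions were AT4G27250, AT2G35390 and AT4G16410, at -0.03, -1.62 and -0.42 relative to WT on the log2 scale. The count of 11 is no independent check, because the same WT measurements served to pick these genes. No such share over all probes is given. The count of 82 was 40 when probes listed at 0 throughout were also left out, and 7 with median centring.

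The second question was whether transcripts of photosystem I moved apart from those of other thylakoid complexes. PSAN, a lumenal subunit of photosystem I and the only one of its complex with a probe of its own, had log2 intensities of 1.55 ± 0.42 in WT and 2.52 ± 0.39 in psag (SD, n = 4 each). The 4 psag measurements were above the 4 WT measurements, but PSAN did not pass across all probes (limma, adjusted p = 0.211). PSBW, a small subunit of photosystem II, had 5.98 ± 0.26 in WT and 4.81 ± 0.83 in psag (SD, n = 4 each; limma, adjusted p = 0.309). The difference of -1.17 was -0.73 without psag replicates 7 and 8. PSBY, another such subunit, differed by -0.53 ± 0.21 (SE) and the antenna gene LHCB1.5 by 0.42 ± 0.16 (SE) on the log2 scale, both with limma adjusted p = 0.349. Adjusted over the list alone, the limma test passed for 1 of 1 measured photosystem I gene, 1 of 1 photosystem II antenna gene and 2 of 2 photosystem II genes, against 0 of each across all probes. For a list of 1 gene this is the unadjusted p. Without psag replicates 7 and 8 it passed for PSAN and PSBW, but not for LHCB1.5 or PSBY (limma, adjusted p = 0.0853 and adjusted p = 0.0886 over the list alone). LHCB1 genes are near-identical copies, so the value for LHCB1.5 can include signal of its relatives. PSAN minus the mean of the other 3 was -2.07 ± 0.15 in WT and -0.67 ± 0.65 in psag (SD, n = 4 each). The difference of 1.396 had p = 0.0286 (exact two-sided permutation test over 70 groupings), the smallest p this design allows. It was 1.08 without psag replicates 7 and 8 (exact permutation p = 0.0286) and 1.31 without WT replicates 7 and 8 (exact permutation p = 0.0571). No other photosystem I subunit or antenna gene of that complex was measured by a probe of its own, so the comparison rests on 1 transcript of photosystem I. The other side held only 2 photosystem II subunits, which moved against PSAN, and 1 photosystem II antenna gene, which moved with it. Of the list of cytochrome b6f, plastocyanin, ferredoxin and ATP synthase, 0 genes had a probe of their own, so these complexes were not compared.

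**Figure D3:**
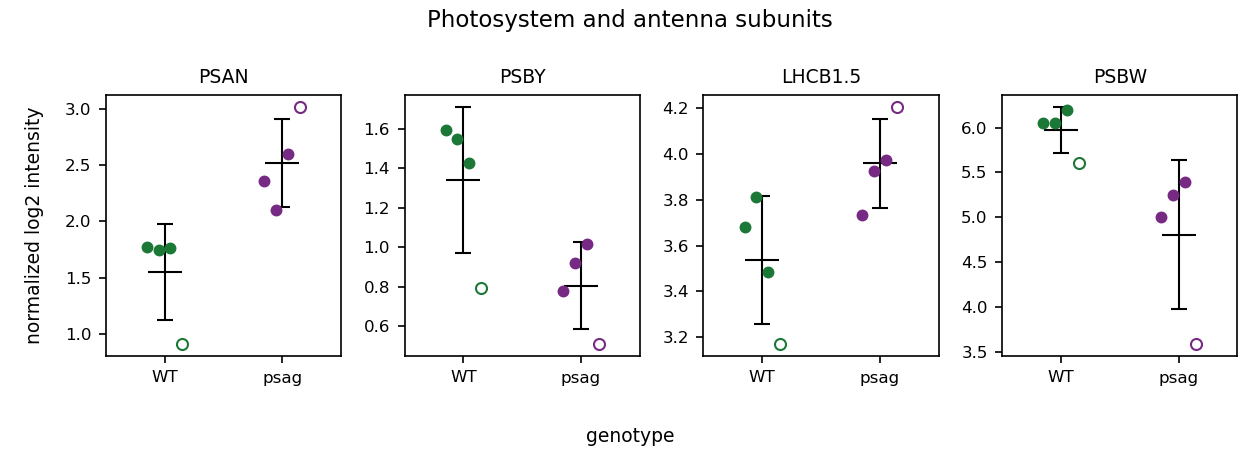
Normalized log2 intensity (vertical axis) of 4 photosystem and antenna transcripts by genotype, with each point a measurement averaged from 2 arrays, open symbols for replicates 7 and 8, and bars for the mean and SD of 4 measurements. Means for PSAN were 1.55 in WT and 2.52 in psag, and those for PSBW were 5.98 and 4.81.

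The third question was whether groups of genes moved together. Of the 6 plastid ribosomal protein genes measured, 0 passed across all probes and 0 passed when adjusted over the list alone (limma). Their median change was -0.03 on the log2 scale, with PRPL5 at 0.40 and PRPL17 at -0.12 as examples (camera, adjusted p = 0.867; adjusted p = 0.884 with an estimated correlation). PRPL34 and PRPS6 were listed at 0 on most arrays of both genotypes. Of the Calvin cycle enzymes, PRK differed by -0.72, and SBPASE was listed at 0 on 7 of 8 WT and 5 of 8 psag arrays, so no change is given for it. Of the chlorophyll synthesis genes, CHLM differed by 0.34 and CHLP by -0.39. The fatty acid synthesis genes AT1G24360 and FATB differed by -0.92 and -0.75, and the branched-chain amino acid genes KARI and DHAD by -0.01 and 0.33. The peroxiredoxin gene PRXIIE differed by -0.06. Without psag replicates 7 and 8, AT1G24360 was at -0.31, FATB at -0.36, CHLM at 0.09, PRXIIE at -0.38 and DHAD at 0.48, while KARI changed sign, to 0.05. None of these 9 genes passed, across all probes or adjusted over the list alone (limma). Markers of senescence, of roots and non-green plastids and of seeds had 0 members with a probe of their own, so the makeup of the tissue was not analysed here.

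Of the lists written after the array's genes were known, the 4 photosystem and antenna genes went both ways, with a median of -0.06. Across all probes 0 of them passed, and 4 of 4 passed when adjusted over the list alone (limma). With replicates 7 and 8 left out, 2 of the 4 passed adjusted over the list alone. Among 16 pentatricopeptide repeat genes, 0 passed across all probes with all measurements, and 1, OTP70, passed when adjusted over the list alone (limma, adjusted p = 0.0154). CRR21, required for editing of a plastid transcript, was at 0.51 ± 0.18 (SE) on the log2 scale (limma, adjusted p = 0.309). AT2G46050 of the same list was at -0.66 ± 0.20 (SE; limma, adjusted p = 0.247), and without psag replicates 7 and 8 it passed with OTP70 over the list alone (limma, adjusted p = 0.0389). With all measurements, 5 of the 16 were higher in psag, with a median of -0.06, and 3 were listed at 0 on most arrays. The histone H3 gene AT5G65360 was 0.58 ± 0.13 (SE) higher in psag (limma, adjusted p = 0.150), and it was the 1 of 3 histone H3 genes that passed adjusted over the list alone (limma, adjusted p = 0.00964). The other histone H3 genes, AT1G13370 and AT1G09200, were at -0.71 ± 0.56 and 0.02 ± 0.25 (SE), with AT1G13370 at -0.12 without psag replicates 7 and 8. Histone H3 copies are nearly identical in sequence. Of the 10 lists tested, 0 passed with camera, 0 with an estimated correlation and 0 with fry. At an unadjusted camera p under 0.05 there were also 0, and the smallest adjusted p was 0.788 with camera and 0.283 with fry. Without psag replicates 7 and 8, fry's test for change in either direction gave adjusted p = 0.0137 for the photosystem and antenna genes, 0.0190 for plastid carbon metabolism and 7.8e-04 for pentatricopeptide repeat genes, while camera's smallest adjusted p was 0.734. For these lists in the same order, camera with an estimated correlation gave adjusted p = 0.985, 0.847 and 0.985, and fry's test for movement in 1 direction gave adjusted p = 0.822, 0.0844 and 0.990. Unlike camera, fry does not compare a list with other genes. In this fit 625 of 3438 probes, or 18.2%, had an unadjusted limma p under 0.05, so passing fry does not set these lists apart from the rest. Without that pair, 1 of 4 plastid carbon metabolism genes, PPDK, passed over the list alone (limma, adjusted p = 0.0229). It was at -0.33 on the log2 scale, against 0.11 with all measurements, while NADP-MDH of the same list was at 0.38 without the pair.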

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

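The split counts were planned before their results were seen; the tests of psag replicates 7 and 8 were chosen only after these arrays were seen to stand apart. Of 36 groups of 4 measurements examined for a value far from the other 3, 8 held one, where chance gives about 1 in 20. Of these, 4 concern genes named only because they passed without psag replicates 7 and 8, which favours that pair lying apart, so their number is no evidence. Of the other 16 groups 4 held such a value, where chance gives about 0.80, and that pair was the distant one in 2. As a share of the range, the gap was 0.968 for the mean correlation with the other psag measurements, 0.954 for SIS, 0.905 for AT4G27250, 0.872 for AT2G35390, 0.858 for AT3G20150 and 0.855 for AT4G16410. For PSAN in WT the gap was 0.968, with WT replicates 7 and 8 at 0.91 and the other 3 at 1.75 to 1.77. For AT1G28150 in WT it was 0.914, with WT replicates 1 and 2 at -2.43 and the others near -2.77.

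Psag replicates 7 and 8 differed from the mean of the other psag measurements by 4-fold or more at 209 probes, against 5 to 28 for the other 7 measurements. Of the 209, 157 were lower and 52 higher in this pair. Noise of single spots and noise of faint probes are each argued against by their own test. The deviations of both arrays correlated at 0.836 across probes, where the mean they share would give about 0.143 for unrelated arrays. Among the brightest 25% of probes their SD was 3.93 times the largest of the other psag measurements. Noise shared by the pair, as from labelling or hybridisation, could give both values and was not tested. Of all arrays, these had the lowest sums, 2314 and 2367, and the lowest median intensities, 0.175 and 0.172. A swap with WT replicates 7 and 8 would put those at the psag level, but over the 49 probes that separated the first 3 measurements of each genotype they lay at -0.0829 between WT at 0 and psag at 1 (quartiles -0.359 and 0.163). WT RNA under a psag label cannot be told apart from psag RNA: the position of the pair, 0.550, met the bound written for excluding it but had quartiles of -0.0705 and 1.49, the pair lay in the psag direction at 34 of the 49 probes against 16 for WT replicates 7 and 8, and the low correlation with WT, at most 0.834, decides nothing because the correlation with psag was low too. Different growth or handling of this psag sample stays open and untested.

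Splits that take no account of the replicate numbers argue against chance for the count of 11 probes, but cannot exclude it. Of the 35 splits of the 8 measurements 1, the real one, gave as many, and the highest of the others gave 1. With 35 splits, 1 is the smallest number that can be reached. These splits ignore the resemblance between arrays of one number. With averaged pairs of the same numbers as a block, 0 of the 11 passed. For the 82 probes without psag replicates 7 and 8, 1 of 35 splits gave as many, and the highest of the others gave 4. The same limits hold for that count. Leaving that pair out was itself a choice made after seeing the arrays.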

How the results depend on the processing

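Settings that left out pairs, took 16 separate arrays or left out probes listed at 0 were chosen after seeing the data. The count of 11 probes (9 higher, 2 lower) depended on most choices, and the cause was not tested except where stated. It was 6 (6 higher, 0 lower) with the lower pseudocount, and 4 probes were lower with the higher one. It was 0 with median centring (0 higher, 0 lower), while without normalization 1 probe was lower and 3 of its 14 probes were among the 11. It was 3 (2 higher, 1 lower) without the dimmest 25% of probes, 2 (2 higher, 0 lower) with limma-trend, and 102 (67 higher, 35 lower) with array weights. Pairs as a random block gave 113 (70 and 43), and 16 separate arrays gave 330 (195 and 135). Without probes listed at 0 throughout it was 2 (2 and 0). Those probes have no spread, and with them the variance shared across probes in limma was 0.0279, against 0.120 without. Leaving out psag replicates 7 and 8 as well gave 40 (32 and 8), and with median centring 7 (7 and 0). Leaving out 1 array gave 3 to 13 probes (3 to 10 higher, 0 to 5 lower): 3 without psag replicate 7, 5 without WT replicate 1 or 4, and 7 without WT replicate 8. Leaving out 1 pair gave 0 to 82 (0 to 55 higher, 0 to 27 lower), with 82 without psag replicates 7 and 8, and 0 without WT replicates 1 and 2, 5 and 6 or 7 and 8 or psag replicates 1 and 2.

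Averaged pairs of the same numbers as a block gave 1 probe (0 higher, 1 lower), with 0 of the 11 among it. The photosystem I difference stayed at 1.396 with an exact permutation p = 0.125, the smallest that sign changes of 4 pairs allow. This block has 4 pair positions, not 8 single numbers, and leaves fewer degrees of freedom for the test. Deviations of WT and psag arrays of one number correlated at 0.0514 to 0.206, over 0.1 for 5 of 8 numbers, so the requirement of over 0.1 for each number was not met. Below it were number 1, at 0.0841, and numbers 7 and 8, at 0.0514 and 0.0632. The latter hold the psag pair that stood apart, which can hide shared conditions there and shifts the psag mean used for the other numbers. The requirement therefore cannot exclude conditions shared by number. Still, 6 of 8 WT and 6 of 8 psag arrays correlated best with their own number. That is a sign of conditions shared by number, which the labels do not state and the main fit leaves out. The photosystem I difference ranged from 1.08 to 1.60 over 35 alternatives and missed the threshold in 2: under the block, and at 1.31 without WT replicates 7 and 8. Without 1 array it was 1.37 to 1.43. The 4 passing named genes kept their direction in all 39 alternatives, but missed the threshold in 8 (AT5G52810), 16 (SIS), 25 (AT4G23080) and 19 (AT1G06730) of them. Of the 8 fits without 1 pair, they passed in 2, 1, 1 and 2. Quantile normalization repeats the main setting, and limma-trend and the blocks change only the test, so these alternatives could not change a direction. AT2G35390 reversed to -0.14, -0.03 and -0.07 without psag pairs 1, 2 and 3, and was 0.69 without pair 4. With camera, no list passed in any of 37 alternatives, and fry was run in only 1 of them, without psag replicates 7 and 8, where its test for change in either direction passed 3 lists. That test does not compare a list with other genes. The PSAG result was not run, for want of a named probe. Array weights and limma-trend gave no permutation value. Intensities near 0 limit dim probes, with no background measure analysed here.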

Other observations

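The genes given here, examples of large differences at psag replicates 7 and 8 among single-gene probes above the median level, were chosen after their values were seen. AT1G02020 had a log2 intensity of 2.31 there, against -1.92 ± 0.55 in the other psag measurements (SD, n = 3) and -0.63 ± 0.71 in WT (SD, n = 4). PPDK, which makes phosphoenolpyruvate from pyruvate, was at 0.59 against -1.19 ± 0.04 (SD, n = 3). AT5G40030 was at -1.51 against 2.05 ± 0.34 and AT1G16080 at -0.47 against 2.64 ± 0.05 (SD, n = 3 each). AT2G26110 was listed at 0 on both arrays and at 0.371 to 1.48 on the other 14. A probe with several genes, at 98.8 to 100 on the other 14 arrays, read 6.06 and 5.22 on these.

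By list, all 4 plastid carbon metabolism genes were above the other psag measurements in this pair, with a median of 0.74 on the log2 scale, and 4 of 5 mitochondrial respiratory chain genes were, with a median of 1.13. The 4 include SBPASE, listed at 0 on 7 of 8 WT and 5 of 8 psag arrays. The 5 include AT5G47030, listed at 0 on all 8 WT and all 8 psag arrays. Of 16 pentatricopeptide repeat genes, 10 were lower and 4 higher. Of 7 transcriptional regulators, 5 were higher, with a median of 0.58, and 4 endoglucanase genes went both ways, with a median of -0.40. Shares over all probes are not given beside these counts. These shifts concern a single measurement and were not tested.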
